A study of Mus musculus with 2 samples.

How the data were processed

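Single-cell RNA sequencing libraries of the mouse mammary gland were used, 1 from control mice (K14-cre; P4HA1 fl/+) and 1 from knockout mice (K14-cre; P4HA1 fl/fl). Each library was made from 3 pooled mice of 8 weeks, per the labels. Glands were digested with collagenase and hyaluronidase, red blood cells were lysed, cells were digested briefly with trypsin, dispase and DNase, propidium iodide was used to detect dead cells, and equal numbers of sorted cells were loaded on the 10x Genomics Chromium platform, per the labels' protocols. The deposited values are raw UMI counts per gene and cell barcode, made with Cell Ranger 6.1 on the mouse build mm10 (GRCm38), per the submitters' processing notes. The chemistry, the annotation release and the options of that tool are not given in the sources used here. The matrices hold the barcodes that had been called cells, and the smallest barcode had 500 UMIs in both libraries.

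The control library held 8500 barcodes with 45352845 UMIs and the knockout library 5519 barcodes with 41734344 UMIs. Cells were kept with at least 500 genes and at most 10% mitochondrial UMIs. In the control 1192 barcodes lay under the gene minimum and 846 above the mitochondrial limit, and in the knockout 569 and 611. Doublets were scored per library with the Scrublet method, rewritten with exact nearest neighbours, at an expected rate of 0.8% per 1000 barcodes, and 185 control and 83 knockout barcodes past the automatic threshold were removed. The remaining 6798 control and 4602 knockout cells were clustered together without integration: counts per 10000, log1p, 2000 variable genes, 30 principal components, 15 nearest neighbours with shared-neighbour weights, and Leiden clustering at resolution 1, which gave 38 clusters. A cluster took the class whose markers had the highest mean difference from all other cells, from 20 marker lists, if at least 3 markers were detected in at least 10% of its cells. It stayed unnamed where its 10 top genes held more markers of another class, or as many of the class next in score, or where no marker was among the top genes and most were undetected.

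This naming score was set after seeing the data, on marker lists written earlier, and so was a further rule. Barcodes outside the immune classes with at least 3 of the macrophage markers detected and at least 10 UMIs of these markers per 10000 were taken out of their class and are called mixed with macrophage. A limit of 5, tried first, also caught basal cells whose macrophage UMIs were at the level of free RNA. The mixed barcodes made up 585 control and 387 knockout barcodes. Of the barcodes clustered as hormone-sensing, 38.6% in the control and 39.5% in the knockout were mixed, of those clustered as luminal progenitor 53.1% and 38.5%, and of those clustered as basal 5.54% and 0.541%. Between 5 and 20 marker UMIs per 10000, near the limit, lay 114 control and 82 knockout hormone-sensing, 69 and 20 luminal progenitor, and 204 and 17 basal barcodes.

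With 1 library per group no test between the groups was possible, and cells were not used as replicates. Shares of cells are given with exact (Clopper-Pearson) 95% intervals, UMI sums with exact Poisson intervals, and ratios of sums with the exact conditional binomial interval. All of these cover counting error only. UMI sums per class were scaled to the total UMIs of the class (CPM), and log2 ratios of knockout over control used a pseudocount of 1 CPM, except for single collagen-modifying enzymes, whose ratios of CPM carry none. Genes with at least 30 UMIs over both libraries in a class were kept. Because the median log2 ratio of all these genes lay above 0 in every class examined, gene and list values are given relative to that class median. For each of 33 gene lists with at least 4 measured members, the median was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries and is no test of the groups. Intervals of list medians come from 1000 Poisson draws. Lists were computed in 7 classes.

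Named genes follow a rule fixed, like the cell filter, the markers, the gene lists and the first group of other settings below, before the data were examined. Among genes with at least 50 CPM in the higher library, the 12 largest and 12 smallest ratios were taken in basal cells and 6 of each in luminal progenitor, hormone-sensing and fibroblast cells. The counting interval had to exclude a 1.5-fold difference in the direction of the change, on ratios not yet set against the class median, so that fewer lower than higher genes can pass, and the gene had to reach at least 0.2 of its CPM in the highest class, as a guard against free RNA. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes, Xist, Y-linked genes and unnamed models were left out. From each list up to 4 members are named, the 2 largest and 2 smallest ratios among members with at least 50 CPM. Shares of cells with a UMI were taken after every cell was thinned to 2000 UMIs, leaving out shallower cells, and in a later check to 2000 UMIs without the ribosomal RNA-like models and Lars2. Gene positions are from GENCODE vM21 on GRCm38, in which 32158 of the 32285 gene IDs of the matrices were found.

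The counting steps were tested on simulated sums built from the 1818 cells with at least 3 UMIs of Krt14 and Krt5 together, with 200 genes changed by known folds among 11882 genes. The sums were independent Poisson draws per gene, as the intervals assume. This checks the computation only, and not how the steps do where a few cells hold many UMIs of a gene. The intervals held the true value for 95.5% of unchanged genes. Of genes with at least 50 CPM, 100% of those raised 2-fold or 4-fold and 92.3% of those lowered to 0.5 met the 1.5-fold rule, against 0% of those raised 1.5-fold and 0% of the unchanged. Of 500 unchanged lists, 4.40% lay outside the central 95% of random lists.

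Other settings fixed beforehand were a lenient filter (200 genes, 20% mitochondrial UMIs), a strict filter (1000 genes, 5%; under both filters the automatic doublet threshold marked under 0.5% of knockout cells, so the highest scores up to the expected rate were removed there, 213 and 89 cells), doublets kept, Leiden resolutions 0.5 and 2, removal of clusters with over 90% of their scaled cells from 1 library, median-of-ratios scaling, equal weight per cell, thinning, subtraction of free RNA, a pseudocount of 10 CPM, and gene minimums of 100 and 1 UMIs. The share of free RNA was set per library from 8 epithelial genes in immune cells. Immune cells were not cleared of barcodes that also hold epithelial transcripts. Krt14 alone stood at 33.7 CPM in control and 9.90 CPM in knockout macrophages. That gap is wider than between the estimated shares of 9.24% and 6.03%, so the subtraction may leave free RNA behind. Added after seeing the data were mixed barcodes kept in their class or taken from 5 marker UMIs per 10000, the cluster of mixed luminal identity counted as either luminal class, totals without the ribosomal RNA-like models, basal cells without their proliferating cluster, knockout basal cells weighted so that the 4 basal clusters of resolution 2 have the control's mix, the same weighting in the other 6 classes, and list members under 0.2 of the highest class left out. The clusters were formed on the same counts, so this weighting can also take away a difference within cells. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, scikit-image 0.26.0 and leidenalg 0.10.2.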

Results

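Cells of the mouse mammary gland were profiled in 1 control library and 1 knockout library, each from 3 pooled mice. P4HA1 is a catalytic subunit of collagen prolyl 4-hydroxylase, which modifies proline residues of collagen chains, and K14-cre is active in cells that use the keratin 14 promoter, which in this tissue are mainly basal (myoepithelial) cells. The control mice carried 1 floxed P4ha1 copy together with the recombinase, so the genotype labels set 2 floxed copies against 1. How far the copies were deleted, and whether luminal cells carry the deletion as well, was not measured. The control library had 45352845 UMIs in 8500 barcodes (median 4370) and the knockout library 41734344 UMIs in 5519 barcodes (median 5856). After filtering, 6798 control cells had a median of 5170 UMIs and 4602 knockout cells a median of 6942.5. No difference given here has a replicate check, and every interval covers counting error only.

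P4ha1 (ENSMUSG00000019916, chromosome 10, 59323296 to 59373304, plus strand, GRCm38) was lower in basal cells of the knockout library. It had 102 UMIs in 1023 control basal cells, or 16.9 CPM (counts scaled to the total of the class; 13.7 to 20.5), and 60 UMIs in 552 knockout basal cells, or 10.4 CPM (7.93 to 13.4), a ratio of 0.617 (0.441 to 0.857). Fibroblasts, the class with the highest level, had 118 CPM in the control and 121 CPM in the knockout, a ratio of 1.02 (0.894 to 1.17). Levels in macrophages were 29.4 and 28.9 CPM, in endothelial cells 31.5 and 32.4 CPM, and in dendritic cells 23.6 and 23.6 CPM. Over the other settings the log2 ratio ranged from -0.25 to 0.03 in macrophages, from -0.33 to 0.15 in endothelial cells and from -0.23 to 0.82, the last with thinning, in dendritic cells. Pericytes or smooth muscle cells (21 and 36 UMIs), NK or innate lymphoid cells (6 and 10 UMIs), luminal progenitors (9 and 5 UMIs) and hormone-sensing cells (16 and 18 UMIs) had too few UMIs to show a difference. Over all kept cells P4ha1 stood at 32.3 CPM in the control and 27.4 CPM in the knockout. None of these P4ha1 values is set against the class median. The median log2 ratio of all genes was 0.27 in basal cells, 0.21 in fibroblasts, 0.20 in macrophages, 0.28 in endothelial cells and 0.21 in dendritic cells. Relative to it P4ha1 would stand lower in each class.

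In basal cells thinned to 2000 UMIs each, 3.05% (2.07 to 4.32) of 984 control cells and 2.21% (1.15 to 3.83) of 543 knockout cells had a P4ha1 UMI, with 39 and 9 shallower cells left out. Thinned to 2000 UMIs without the ribosomal RNA-like models described below, the shares were 5.31% (3.97 to 6.95) of 941 and 1.87% (0.902 to 3.42) of 534 cells, from 50 and 10 cells. Each thinning was 1 random draw, and the intervals overlapped in the first thinning but not in this one. In the later thinning fibroblasts had 25.2% (21.5 to 29.2) in the control and 21.0% (16.7 to 25.8) in the knockout. Macrophages had 7.79% and 7.95%, and endothelial cells 7.36% and 7.30%. The unthinned shares of basal cells were 8.99% at a median depth of 5470 UMIs and 9.96% at 9048.5 UMIs. No class can be taken to lack P4ha1; the lowest, hormone-sensing cells, had 0.575% and 1.40% after thinning, at median depths of 9583 and 13592 UMIs. For comparison, Krt14, which macrophages should lack, was found in 3.12% of thinned control macrophages and 1.30% of thinned knockout macrophages (5.14% and 2.16% unthinned, median depths 4342.5 and 5429 UMIs). The labels do not say which exon is flanked by loxP sites, and tags from outside the deleted part do not report the deletion, so the P4ha1 level checks the genotype labels only in part. The log2 ratio of P4ha1 in basal cells was -0.70, or -0.97 (-1.45 to -0.49) relative to the median of all basal genes. Without that shift it ranged from -0.42 with the strict cell filter to -0.79 with mixed barcodes kept, and median-of-ratios scaling, which applies nearly the same shift, gave -0.99.

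**Figure D1:**
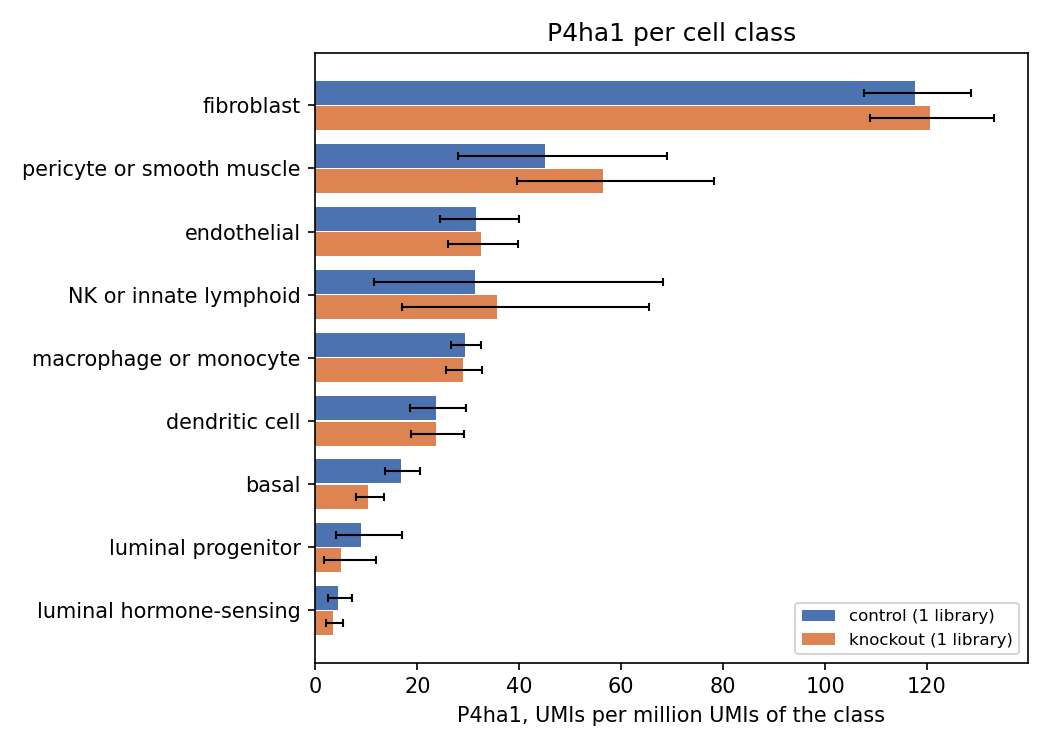
P4ha1 level per cell class in CPM, with control and knockout bars (1 library each) and exact 95% Poisson intervals as error bars. Basal cells read 16.9 and 10.4, while fibroblasts read 118 and 121.

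The shares of epithelial cell classes differed between the libraries. Basal cells made up 66.6% (64.2 to 69.0) of 1535 control epithelial cells and 52.9% (49.8 to 56.0) of 1043 knockout epithelial cells. Hormone-sensing luminal cells, which carry the estrogen and progesterone receptors, made up 24.1% (22.0 to 26.3) and 35.6% (32.7 to 38.6), and luminal progenitors 9.25% (7.85 to 10.8) and 11.5% (9.63 to 13.6). Epithelial cells together were 22.6% and 22.7% of all kept cells, but differed by -5.66 points with the strict cell filter. Within the basal class the cluster with the highest level of proliferation genes held 45 of 1023 control cells (4.40%, 3.23 to 5.84) and 67 of 552 knockout cells (12.1%, 9.53 to 15.2). At a finer resolution the class split into 4 clusters with unequal mixes, of 334 control and 259 knockout, 417 and 99, 227 and 126, and 45 and 68 cells. A basal value below can therefore come from a different mix of cells as well as from a difference within cells. With the strict cell filter the basal share differed by -22.9 points in place of -13.7, the hormone-sensing share by 18.1 in place of 11.5 and the luminal progenitor share by 4.80 in place of 2.25, and with mixed barcodes kept in their class the luminal progenitor share differed by -0.927 points. The strict limit of 5% mitochondrial UMIs lies near the median share of knockout basal cells (4.87%, against 3.63% in control basal cells). It can therefore remove a larger part of the knockout basal cells.

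Among the other classes, macrophages or monocytes were 38.1% (36.9 to 39.3) of kept control cells and 30.2% (28.9 to 31.6) of kept knockout cells. Endothelial cells were 7.36% (6.75 to 8.00) and 10.8% (9.94 to 11.8), and dendritic cells 9.33% (8.65 to 10.0) and 11.2% (10.3 to 12.1). Fibroblasts were 8.00% and 7.48%, B cells 0.515% and 1.20%, NK or innate lymphoid cells 0.765% and 1.46%, and neutrophils 0.530% and 0.956%. Equal numbers of sorted cells were loaded, so a share in a library is not a number of cells in the gland. With the strict cell filter the macrophage share differed by -4.57 points in place of -7.87 and the dendritic cell share by 4.43 points in place of 1.86. The immune share of all kept cells, 49.9% and 45.6%, changed the sign of its difference with the strict cell filter, from -4.32 to 2.01 points.

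**Figure D2:**
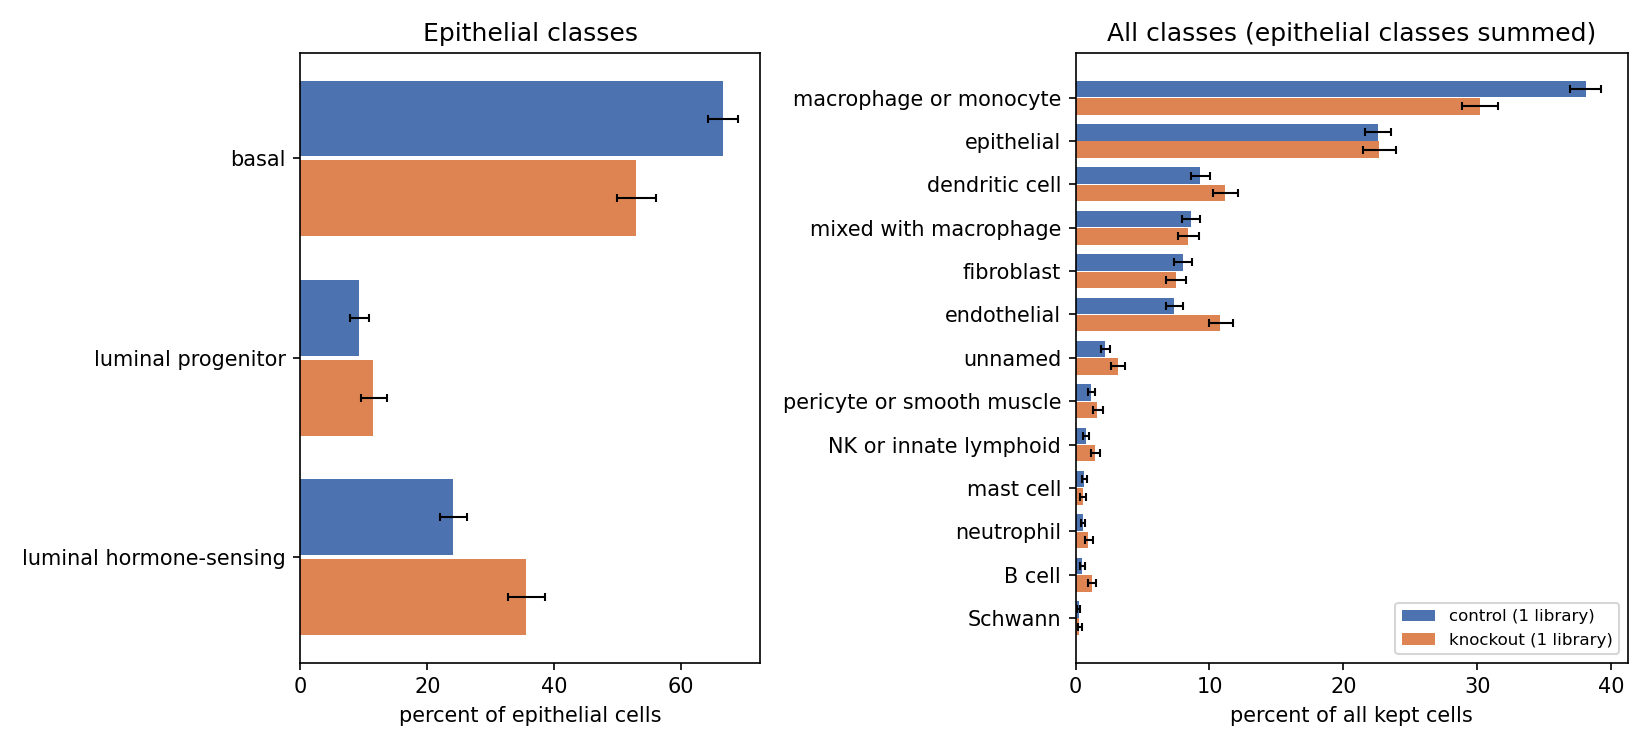
Percent of epithelial cells in each epithelial class (left) and percent of all kept cells in each class (right), control and knockout bars (1 library each) with exact 95% binomial intervals as error bars. Basal cells read 66.6% and 52.9% of epithelial cells, and hormone-sensing cells 24.1% and 35.6%.

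A sum of 4 genes, chosen after their values were seen, was lower in the knockout library in every class examined. Gm42418 and AY036118, overlapping models on opposite strands of chromosome 17 (39846958 to 39848788 and 39847113 to 39848035) that collect reads of ribosomal RNA, the neighbouring model Gm26917 and the mitochondrial leucyl-tRNA synthetase gene Lars2 together took 26.4% of basal UMIs in the control and 11.8% in the knockout. In macrophages they took 28.9% and 17.2%, and in fibroblasts 25.4% and 15.3%. Gm42418 made up most of the sum (25.6% and 11.6% of basal UMIs), while Gm26917 alone had log2 ratios of 0.59 in fibroblasts and 0.15 in luminal progenitors. The median log2 ratio of all genes was 0.27 in basal cells, 0.28 in luminal progenitors, 0.22 in hormone-sensing cells and 0.21 in fibroblasts. Gene and list values below are relative to the median of their class.

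In basal cells, the class in which the series description places the silencing, most genes named as higher belong to the cell division machinery. Only the 12 largest ratios are named in this direction, and many more genes met the rule. Ube2c, which marks mitotic regulators for destruction, stood at 23.1 CPM in the control and 105 CPM in the knockout, a relative log2 ratio of 1.87 (1.65 to 2.19). The centromere genes Cenpe, at 1.93 (1.67 to 2.38), Cenpf, at 1.42 (1.21 to 1.71), and Cenpa, at 1.34 (1.07 to 1.73), the spindle gene Prc1, at 1.41, the proliferation marker Mki67, at 1.37, the condensin gene Smc2, at 1.36, and the mitotic kinase gene Cdk1, at 1.36, were also higher. All 20 members of the proliferation list lay above the class median, with a list median of 1.30 (1.09 to 1.37) at the 100 percentile. Pcna, with 132 and 187 CPM, had the smallest ratio of its measured members at 50 CPM or more, 0.23. Without the proliferating cluster the list median was 0.64, Cenpe was at 1.17, Smc2 at 0.88, Mki67 at 0.77, Prc1 at 0.64, Cenpf at 0.41 and Ube2c at 0.21, and with a pseudocount of 10 CPM the list median was 0.85. With the 4 finer clusters weighted to the control's mix it was 0.36, with Cenpe at 0.84, Ube2c at 0.71, Smc2 at 0.60, Cenpa at 0.51, Cdk1 at 0.36, Prc1 at 0.32, Mki67 at 0.28 and Cenpf at 0.23. Within the finer clusters the list median was 0.09 (9 measured members), 0.10 (4) and 0.78 (10), and -0.11 (20) in the cluster of 45 control and 68 knockout cells.

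Outside cell division, basal cells of the knockout library had more Pthlh, which encodes parathyroid hormone-related protein (13.6 and 55.6 CPM, relative log2 1.69), Nes, which encodes the intermediate filament nestin (20.8 and 72.8 CPM, 1.49), Sema3b, a secreted semaphorin gene (1.20), and S100a14, a calcium-binding protein gene (1.20). The 1.5-fold rule acts on ratios before they are set against the class median of 0.27, which lets fewer lower than higher genes pass. Beside Lars2 (-2.01) and AY036118 (-1.80), it left Nrep (-1.41, 69.1 and 30.8 CPM), the translation initiation factor gene Eif3j1 (-1.20), the nuclear RNA Malat1 (-1.05), the cytokine gene Il17b (-1.05, 500 and 291 CPM) and the amino acid transporter gene Slc38a2 (-0.93) as lower. No other gene among those considered met the rule as lower, while the genes named as higher are only the largest ratios. With the finer clusters at the control's mix Il17b was at -0.66.

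Genes of collagen modification, as a list, showed no shift in basal cells. Of its 17 measured members 9 lay above and 8 below the class median, and the list median was 0.01 (-0.11 to 0.11) at the 47.0 percentile. P4hb, the partner subunit of P4HA1, stood at 175 and 209 CPM (-0.01, -0.13 to 0.11), and P4ha2, the other main catalytic subunit, had 21 and 26 UMIs (0.11, -0.78 to 1.01). The lysyl hydroxylase genes Plod1, at -0.49 (-0.90 to -0.09), and Plod2, at -0.51 (-0.80 to -0.22), and the prolyl 3-hydroxylase gene P3h2, at -0.44 (-0.82 to -0.07), were lower. Ppib, at 0.26 (0.17 to 0.36), and P3h4, at 0.43 (0.07 to 0.80), were higher, while the collagen chaperone gene Serpinh1 was at -0.09 (-0.19 to 0.01). Plod3 (0.22), P3h1 (-0.08), P3h3 (0.02), Crtap (0.21), Fkbp10 (-0.15), Fkbp14 (0.37) and Mia3 (0.03) had intervals that include 0, and Colgalt1 was at 0.17 (0.01 to 0.33). P4ha3 had 0 UMIs in control and 2 in knockout basal cells. With the strict cell filter the list median was -0.14.

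Basement membrane and fibrillar collagen genes were lower on balance in the basal class. The basement membrane list, genes of laminins, type IV collagen and their partners, had 16 of 19 measured members below the class median and a median of -0.25 (-0.36 to -0.19) at the 0.10 percentile, with Col4a5 at -0.73 (179 and 129 CPM) and Nid1 at -1.22 (65.5 and 33.3 CPM) the lowest and Col18a1 at 0.35 (110 and 170 CPM) the highest. Nid1 in control basal cells was at 0.05 times its level in the highest class. The list of fibrillar and associated collagens had a median of -0.48 (-0.67 to -0.24) at the 0.03 percentile, with 8 of 11 members below the class median. Its 4 members with at least 50 CPM reached from -0.48 (Col12a1) to 0.13 (Col14a1), and the 5 members below the list median all had under 50 CPM. A lower collagen list was not particular to basal cells. It was at -0.89 in hormone-sensing cells but 0.08 in fibroblasts. Over the other settings it ranged from -1.19 to -0.21 in macrophages and from -0.78 to -0.01 in endothelial cells. Free RNA from fibroblasts was not told apart from transcripts of the basal cells themselves. With a pseudocount of 10 CPM the basement membrane median was -0.15, and with free RNA subtracted the collagen median was -0.28. With the finer clusters at the control's mix the medians were -0.28 (basement membrane) and -0.44 (collagens), and within single clusters they ranged from -0.47 to -0.07 and from -0.41 to 0.04. The matrix remodelling list was at -0.12 (10.6 percentile), although the matricellular gene Thbs1 was at -0.57 and the protease gene Adamts1 at 0.67.

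Oxidative phosphorylation, glycolysis, heat shock and WNT genes were higher on balance in basal cells. All 20 oxidative phosphorylation genes lay above the class median, with a list median of 0.45 (0.40 to 0.54) at the 100 percentile, and cytochrome c, Cycs, at 0.90 and Atp5g1 at 0.88 the highest. Glycolysis genes were at 0.24 (97.7 percentile, 11 of 15 above), with Pgam1 at 0.73 and Gapdh at 0.67, while Hk2 was at -1.63. The dissociation stress list (0.26, 99.6 percentile, 16 of 20 above) and the heat shock list (0.29, 99.0 percentile, 11 of 12 above) included Hspa1a at 0.88, and the WNT list (0.27, 98.9 percentile, 12 of 17 above) included Ccnd1, the cyclin D1 gene, at 1.30. Hk2 in control and Ccnd1 in knockout basal cells lay under 0.2 of their level in the highest class, the guard against free RNA. Fibroblasts had Hk2 at 450 CPM in the control and 209 CPM in the knockout. With the finer clusters at the control's mix the dissociation stress list was at 0.39 and the WNT list at 0.10. Within single clusters oxidative phosphorylation ranged from 0.15 to 0.54, glycolysis from 0.19 to 0.36, dissociation stress from 0.07 to 0.68, heat shock from 0.21 to 0.35 and WNT from 0.06 to 0.55. The median share of mitochondrial UMIs in basal cells was 4.87% in the knockout and 3.63% in the control library. It was higher in the knockout in every class with lists, as in endothelial (3.40% against 2.58%) and hormone-sensing cells (4.18% against 3.31%). These shares are not set against a class median.

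NF-kB, p53, TGF-beta and YAP target genes were lower on balance in the basal class as a whole, but only the NF-kB list was below the median in all 4 finer clusters. The NF-kB and acute phase list was at -0.33 (0.06 percentile, 11 of 14 below), with the adhesion gene Icam1 at -0.59 and Cebpd at 0.34. The apoptosis and p53 list was at -0.32 (0.09 percentile, 12 of 16 below), with Cdkn1a at -0.46 and Bax at 0.68, the TGF-beta target list at -0.21 (1.825 percentile), with Skil at -0.40, and the YAP and TEAD target list at -0.26 (1.425 percentile), with Crim1 at -0.46. MHC class II genes were at -0.76 (6 of 6 below), but Cd74 in control basal cells was at 0.02 times its level in the highest class. The luminal progenitor identity list was at -0.50 (0.03 percentile), with Mfge8 at -0.64, and the hormone-sensing identity list at -0.41 (0.55 percentile), with Gata3 at -0.26. Both lists hold genes of luminal cells, and in their own classes they were at -0.02 and 0.004. Free RNA, which was estimated at 9.24% of UMIs in the control and 6.03% in the knockout, mattered for the chemokine list, which was at -0.36 (0.10 percentile) and at 0.06 after its subtraction, and thinning moved the hormone-sensing identity list to 0.01 (-0.86 with every gene of 1 UMI or more), the p53 list to -0.13 and the TGF-beta list to -0.06. With list members under 0.2 of their highest class left out the NF-kB list was at -0.15, with every gene of 1 UMI or more the luminal progenitor identity list was at -0.23 and the YAP list at -0.12, and the MHC class II list ranged from -1.34 with the strict cell filter to -0.28 with free RNA subtracted. With the finer clusters at the control's mix the luminal progenitor identity list was at -0.15, the NF-kB, p53 and YAP lists at -0.16, the chemokine list at -0.18 and the TGF-beta list at -0.08. Within single clusters the NF-kB list ranged from -0.26 to -0.05, the p53 list from -0.34 to 0.17, the TGF-beta list from -0.23 to 0.09 and the YAP list from -0.30 to 0.08.

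Basal cells otherwise kept their identity genes near the class median. The basal identity list was at -0.01 (37.3 percentile), with the integrin gene Itgb4 at 0.52 and Egfr at -0.65, and the contractile list at 0.05 (56.3 percentile), with the smooth muscle gamma-actin gene Actg2 at 0.73 and Smtn at -0.35. The HIF and hypoxia list was at -0.02 (37.0 percentile), with Hif1a at -0.42 and Higd1a at 0.43. The mammary stem cell list was at 0.02, the Notch list at -0.03, the MHC class I list at -0.06, the oxidative stress list at -0.07, the epithelial-mesenchymal transition list at -0.07, the list of 2-oxoglutarate dioxygenases at -0.10, the interferon list at -0.17, the senescence list at -0.20, the milk list at -0.32, the unfolded protein response list at 0.11, the luminal keratin list at 0.17 and the cholesterol list at 0.17, all within the central 95% of random lists. Within single finer clusters the basal identity list ranged from -0.02 to 0.03. Other lists ranged more widely, as the contractile list from -0.22 to 0.28. The mammary stem cell list ranged from -0.23 to 0.42 and the Notch list from -0.34 to -0.04.

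**Figure D3:**
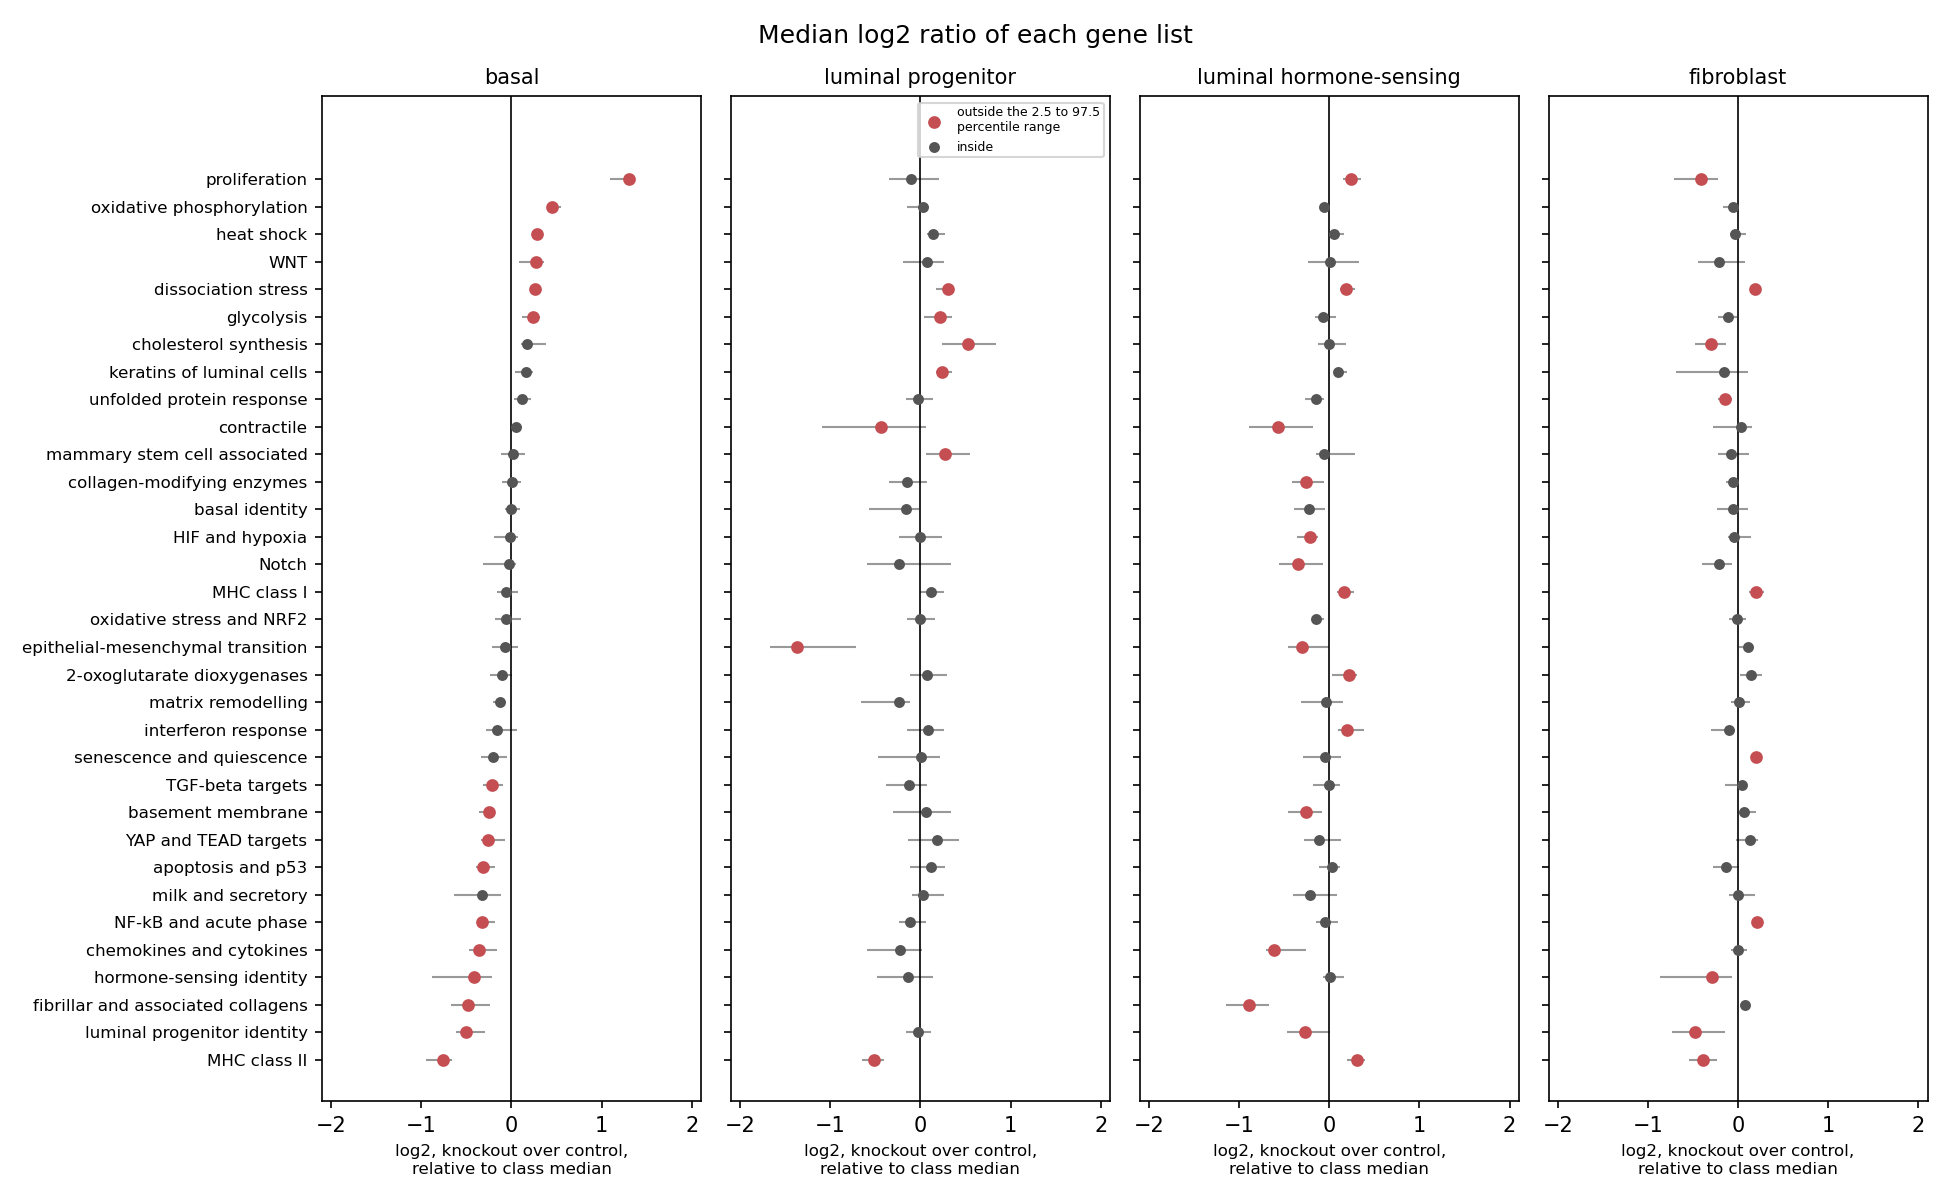
Median log2 ratio (knockout over control) of each gene list relative to the median of all genes of the class, in basal, luminal progenitor, hormone-sensing and fibroblast cells (1 library per group). Lines are 95% counting intervals, red points lie outside the central 95% of random lists, and the proliferation list stands at 1.30 in basal cells and -0.10 in luminal progenitors.

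In luminal progenitors (142 control and 120 knockout cells), cholesterol synthesis and luminal keratin genes were higher on balance. The cholesterol synthesis list had a median of 0.52 (0.24 to 0.84) at the 99.98 percentile, with 8 of 10 members above the class median and Hmgcs1 at 1.41 (20.8 and 69.3 CPM). Luminal keratin and adhesion genes were at 0.24 (99.3 percentile, 9 of 10 above), with Epcam at 0.40 and Krt18 at 0.39, and the dissociation stress list was at 0.30 (17 of 20 above), with Fosb at 0.62. Apod (1.47), Plk3 (1.30), Mapkapk3 (1.28), Nup54 (1.22) and Tmem41b (1.21) were the other genes named as higher, although 1 knockout cell held 34.4% of the Apod UMIs. The Notch target gene Hes1 (-1.73), the endothelin gene Edn1 (-1.68) and the RNA Snhg9 (-1.64) were lower, and Olfr655 (59 and 1 UMIs) met the rule through 1 control cell that held 98.3% of its UMIs. With mixed barcodes kept, Apod was at 0.95, Hmgcs1 at 0.88, Tmem41b at 0.68 and Nup54 at 0.47, and with thinning Nup54 was at 1.999, Edn1 at -0.78 and Snhg9 at -3.99. With the strict cell filter the dissociation stress list was at 0.14. Glycolysis genes were at 0.21 (98.0 percentile), and at 0.02 with mixed barcodes kept, and the MHC class II list was at -0.51 (0.26 percentile) and 0.07 with the lower limit for mixed barcodes, and 0.03 with finer clusters at the control's mix.

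Further lists stood apart in luminal progenitors, 2 of them mainly of genes with higher levels in other classes. The epithelial-mesenchymal transition list was at -1.37 (-1.66 to -0.71, 0 percentile, 5 of 5 below), with Sparc at -1.92 (72.3 and 22.4 CPM) and Zeb2 at -1.39, but Sparc in control cells was at 0.02 times its level in the highest class, and the list was at -0.28 with free RNA subtracted, -0.44 with mixed barcodes kept and -0.88 with finer clusters at the control's mix. The contractile list was at -0.44 (-1.09 to 0.06, 1.86 percentile), with Tagln at -1.93, and ranged from -1.40 to -0.20 over the other settings. The mammary stem cell list was at 0.28 (0.06 to 0.55, 97.9 percentile, 6 of 7 above), with Aldh1a3 at 0.62 and Sox9 at 0.52, and at 0.17 with the strict cell filter.

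In hormone-sensing cells (370 control and 371 knockout cells), H19, an imprinted long non-coding RNA, had 27 and 385 UMIs (7.54 and 73.8 CPM, relative log2 2.91, 2.51 to 3.69), in 13 control and 37 knockout cells before thinning, and 1 cell held 25.9% of the control and 1 cell 23.9% of the knockout UMIs. The fatty acid receptor gene Ffar4 (1.04), Itih2 (1.10), the tryptophan-degrading enzyme gene Ido1 (1.03, 77.6 and 185 CPM), the potassium channel gene Kcnh1 (1.00) and Ly6d (0.98, 1382 and 3164 CPM) were higher. Wfdc3 (-3.73, 82.4 and 6.33 CPM), Pcp4 (-2.32), the serotonin synthesis gene Tph1 (-1.89, 120 and 37.0 CPM) and haptoglobin, Hp (-1.41), were lower. In the control 26.1% and in the knockout 68.6% of the Pcp4 UMIs came from 1 cell, and after thinning H19 was at 1.67, Ffar4 at 0.69 and Kcnh1 at 1.99. The finer clusters of this class had unequal mixes, of 188 control and 235 knockout, 116 and 63, 25 and 39, and 23 and 25 cells, so differences in it can come from the mix as well. At the control's mix H19 was at 3.21, Ido1 at 0.80, Ly6d at 0.75 and Tph1 at -2.07.

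Among lists in hormone-sensing cells, HIF and hypoxia genes were at -0.22 (0.32 percentile, 12 of 16 below), with Hif1a at -0.55, and Notch genes at -0.34 (0.505 percentile), with Hes1 at -1.28. The collagen-modifying enzymes were at -0.26 (1.32 percentile, 9 of 13 below), with P4ha2 at -0.65 (-1.06 to -0.23) and P4hb at -0.26, and fibrillar collagens at -0.89 (5 of 5 below), with Col8a1 at -0.89 (148 and 92.8 CPM). The 2-oxoglutarate dioxygenase list, which holds other enzymes of the same cofactor class as P4HA1, was at 0.22 (99.5 percentile, 12 of 17 above), with the histone demethylase gene Kdm5b at 0.43, and at 0.13 with a pseudocount of 10 CPM. Dissociation stress genes were at 0.18, MHC class I genes at 0.16, proliferation genes at 0.24 (17 of 20 above, Mki67 at 0.91) and chemokine genes at -0.61 (12 of 15 below, Cxcl1 at -0.90). With free RNA subtracted the fibrillar collagen median was -0.23 and the Notch median -0.18, with thinning the collagen-modifying enzyme median was -0.14 and the MHC class I median 0.27, and with equal weight per cell the chemokine median was -0.14. The proliferation median was 0.02 with the strict cell filter and 0.41 with thinning, and after thinning the shares of cells with at least 3 UMIs of that list, 10.6% (7.60 to 14.4) and 13.1% (9.81 to 17.1), had overlapping intervals. In this class, with mixed barcodes kept the interferon list, at 0.20 (98.8 percentile), was at -0.04, and with the lower limit for mixed barcodes at 0.35.

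Lists of basal and other cells were mostly lower in hormone-sensing cells and depended on the processing. The contractile list was at -0.56 (-0.89 to -0.18, 0.08 percentile), although Tpm1 was at 0.29, and ranged from -1.55 with the lenient filter to -0.05 with mixed barcodes kept. The basement membrane list was at -0.25 (2.29 percentile, 8 of 9 below), with Lama5 at -0.20, and at -0.04 with thinning. The epithelial-mesenchymal transition list, at -0.31 (1.74 percentile), ranged from -0.64 with the lenient filter to 2.97 with free RNA subtracted, and the luminal progenitor identity list, at -0.27 (-0.47 to 0.01, 0.49 percentile) with Cxcl1 at -0.90, from -0.82 with the lower limit for mixed barcodes to 0.38 with free RNA subtracted. MHC class II genes were at 0.31 (99.5 percentile, 7 of 7 above), at -0.10 with the lower limit for mixed barcodes, at 0.50 with thinning and at 1.47 with free RNA subtracted. With finer clusters at the control's mix these last 3 lists were at -0.52, -0.07 and -0.11.

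Fibroblasts (544 control and 344 knockout cells) differed in single growth factor, hormone receptor and metabolic genes. Fgf10, a growth factor gene of the mammary stroma (1.11, 48.7 and 124 CPM), the lipoprotein lipase gene Lpl (0.92, 721 and 1576 CPM), Tmem88 (0.97), Sox4 (0.84), Senp2 (0.82) and the interferon-induced gene Iigp1 (0.80) were higher. The progesterone receptor gene Pgr (-1.49, 95.7 and 39.0 CPM), Nmt1 (-1.38), the hexokinase gene Hk2 (-1.32) and Hes1 (-1.22) were lower. The NF-kB and acute phase list was at 0.21 (99.6 percentile, 10 of 14 above), with Icam1 at 0.56, and the senescence list at 0.20 (98.1 percentile), with Igfbp3 at 0.77 and Cdkn1c at 0.66. Cholesterol synthesis genes were at -0.30 (0.12 percentile, 12 of 15 below), and unfolded protein response genes at -0.15 (1.94 percentile, 14 of 18 below), with Pdia4 at -0.79. Fibrillar collagens were at 0.08 (0.05 to 0.13), and P4ha1 at -0.18 (-0.37 to 0.02). With thinning the cholesterol median was -0.63 (-0.18 with every gene of 1 UMI or more), the senescence median 0.31 and Senp2 at 1.24, and with a pseudocount of 10 CPM the unfolded protein response median was -0.09.

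Other lists in fibroblasts stood on both sides of the class median. Luminal progenitor identity genes were at -0.48 (0.03 percentile) and hormone-sensing identity genes at -0.29 (1.13 percentile), and with thinning they were at 0.02 and 0.04, against -1.02 with the lenient filter and -0.94 with at least 100 UMIs. Both lists hold genes of luminal cells, and free RNA was not told apart from transcripts of the fibroblasts themselves. The luminal progenitor list was also low in basal (-0.50) and hormone-sensing cells (-0.27), but at -0.02 in luminal progenitors. Proliferation genes were at -0.41 (0.47 percentile, 8 of 8 below), with Pcna at -0.53, and at -0.20 with doublets kept, but after thinning only 6 of 517 control and 3 of 328 knockout cells had at least 3 UMIs of that list (1.16%, 0.427 to 2.51, and 0.915%, 0.189 to 2.65). MHC class II genes were at -0.39 (0.245 percentile, 6 of 6 below), with Cd74 at 0.01 times its level in the highest class, and ranged from -1.16 with the lower limit for mixed barcodes to 0.24 with doublets kept. MHC class I genes were at 0.20 (98.4 percentile), with H2-K1 at 0.48, and dissociation stress genes at 0.19 (99.89 percentile, 16 of 20 above), with Socs3 at 0.55 and Egr1 at 0.44.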

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

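The test of depth for proliferation genes, the test of unrelated cells for barcodes with macrophage transcripts and the test of depth for the ribosomal RNA-like models were chosen before their results were seen, and all other tests in this part after the patterns were seen, although subtraction of free RNA was itself a setting fixed beforehand.

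Several gene lists lay above the class median in 1 cell class and below it in another, outside the central 95% of random lists in each, which is what drew attention to them. These differences between classes were not tested. Proliferation genes were at 1.30 in basal cells and -0.41 in fibroblasts, a gap of 1.71, and at 0.24 in hormone-sensing cells, a gap of 0.65 to fibroblasts. The fibroblast value came from 8 members and was -0.20 with doublets kept, and the hormone-sensing value ranged from 0.02 with the strict filter to 0.41 with thinning. After thinning, the shares of cells with at least 3 UMIs of the list had overlapping intervals in hormone-sensing cells (10.6% in the control, 13.1% in the knockout) and in fibroblasts (1.16% and 0.915%, from 6 and 3 cells), so a difference in these 2 classes rests on the list medians alone. MHC class II genes were at 0.31 in hormone-sensing cells, with gaps of 1.07 to basal cells (-0.76), 0.82 to luminal progenitors (-0.51) and 0.70 to fibroblasts (-0.39). These gaps did not hold throughout: with a mixed limit of 5 the list was at -0.10 in hormone-sensing cells and 0.07 in luminal progenitors, with finer clusters at the control's mix at -0.11 and 0.03, and with doublets kept at 0.24 in fibroblasts. Other settings widened them: the list was at 0.50 with thinning and 1.47 with free RNA subtracted in hormone-sensing cells, and at -1.16 with a mixed limit of 5 in fibroblasts. NF-kB and acute phase genes were at 0.21 in fibroblasts and -0.33 in basal cells, a gap of 0.54 (basal value -0.15 with members under 0.2 of their highest class left out), and cholesterol synthesis genes at 0.52 in luminal progenitors and -0.30 in fibroblasts, a gap of 0.83 (fibroblast value from -0.63 to -0.18). The Cd74 level in hormone-sensing cells was 0.04 times that of the highest class, so its MHC class II transcripts need not be its own. Haemoglobin transcripts, which no comparison used, made up 262 CPM of the knockout library (10919 UMIs) and 113 CPM of the control library (5136 UMIs), a difference in unused data that was not tested.

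Proliferation genes in basal cells were weighed against technical causes. After every cell was thinned to 2000 UMIs 23.6% of knockout basal cells had at least 3 UMIs of the list, above the control interval (10.1%, 8.25 to 12.1), so total depth did not explain the difference. Because ribosomal RNA-like models took up more of the control UMIs, cells were also thinned to 2000 UMIs of other genes. The shares were then nearer, 16.6% (14.3 to 19.1) in the control and 26.2% (22.5 to 30.2) in the knockout, but their intervals stayed apart. After free RNA was subtracted the list median was 1.35. The share subtracted was larger in the control (9.24%) than in the knockout (6.03%). This step could therefore hardly lower the value, and it does not decide whether RNA from other cells played a part. It also leaves aside whole cells caught in 1 droplet. A difference between the pooled animals that raised proliferation in every epithelial class alike was not seen, since the higher luminal median was 0.24. In macrophages and dendritic cells the list was first counted as higher too. Over the other settings it ranged from -0.04 to 0.28 in macrophages and from -0.05 to 0.22 in dendritic cells. With finer basal clusters weighted to the control's mix the list median was 0.36, and within the 4 clusters it was 0.09, 0.10, 0.78 and, in the cluster with Hmgb2 and Stmn1 among its top genes, -0.11. The value of 1.30 therefore depends on how many cells each cluster held, and only 1 cluster had a list median above 0.10 within it. Whether deletion of P4ha1 in basal cells raised it could not be decided with 1 library per group, and a difference of animals that reached basal cells alone was not tested.

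Many luminal barcodes also held macrophage transcripts, 38.6% of control and 39.5% of knockout barcodes clustered as hormone-sensing. Most of these came from 1 cluster of 252 control and 283 knockout barcodes, of which 43 and 46 stayed in the hormone-sensing class. The largest hormone-sensing cluster kept 313 of 333 and 303 of 308 barcodes. A luminal progenitor cluster of 164 and 78 barcodes kept 22 and 11. The values of both classes include the barcodes that stayed. If unrelated cells had shared droplets by chance, luminal and basal cells would have been caught alike, but the ratio of luminal to basal was 2.20 with macrophage transcripts and 0.476 without in the control (9.14 and 0.854 in the knockout), and the lowest lower bound of the excess was 3.86 times. Free RNA, which reaches luminal and basal barcodes alike, did not explain them as a whole, because 42.2% of luminal and 13.7% of basal barcodes held macrophage transcripts in the control (38.5% and 5.54% in the knockout), with a lowest lower bound of 2.499 times. For luminal cells and macrophages left together by the digestion, a depth near the sum of both cell types was foreseen, and mixed hormone-sensing barcodes had 0.617 (knockout) and 0.7998 (control) of that sum, between the values foreseen for either case, so this was left undecided. No biological explanation, such as uptake of luminal cells by macrophages, was tested.

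The lower share of the ribosomal RNA-like models and Lars2 was weighed as well. It reached every class, as a difference between the libraries would, with log2 ratios from -1.16 in basal cells to -0.73 in fibroblasts. The limit for this, a distance of 0.5 from the basal value, was set after the pattern was seen. Basal cells had the largest drop, and whether a basal part added to the shared drop was not tested. Deletion of P4ha1 in basal cells alone would leave macrophages near 0, where the log2 ratio was -0.75. Depth per cell did not explain it, because at least 0.799 of the log2 ratio stayed among cells of 5000 to 10000 UMIs. Sample handling and a body-wide effect of the genotype were not separated.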

How the results depend on the processing

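Of the 21 other settings that gave values, 12 were chosen before and 9 after results were seen. Median-of-ratios scaling and totals without ribosomal RNA-like models scale all genes of a class by 1 factor, which cancels in values relative to the class median apart from the pseudocount, so their 566 list and gene values test nothing and are left out here. Of the other 4194 values 3799 kept their sign. By counting error, 3689 stayed inside the interval, 474 left it, and 31 changed the sign of a result first counted as different. The latter include every list value given in this part for endothelial cells, macrophages or dendritic cells. P4ha1 in basal cells ranged from -0.79 to -0.42, apart from -0.99 and -0.96 with these 2 scalings, and the basal share difference from -22.9 to -13.4 points, and the epithelial share difference from -5.66 to 1.02. Removing clusters from 1 library removed none. The cause of each change below was not tested, except that subtraction of free RNA leaves some genes at 0.

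With the lenient filter, hormone-sensing identity was at -0.16 in endothelial cells and -0.64 in macrophages, and epithelial-mesenchymal transition (EMT) genes in macrophages at 0.038. Both filters also came with another doublet rule in the knockout library, so their effects are not separated from it. The strict limit of 5% also lies near the median mitochondrial share of knockout basal cells (4.87%). With the strict filter, shares differed by -22.9 (basal), 4.80 (luminal progenitor), 18.1 (hormone-sensing) and 2.01 points (immune), collagen-modifying enzymes in basal cells were at -0.14, hormone-sensing identity at -0.14 in endothelial cells and -0.15 in macrophages, EMT genes in macrophages at 0.034, and luminal progenitor identity in dendritic cells at 0.069. With doublets kept, MHC class II in fibroblasts was at 0.24, and at resolution 0.5 EMT genes in macrophages were at 0.0059.

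With equal weight per cell, macrophages had hormone-sensing identity at -0.12 and proliferation at -0.041. With thinning, basal proliferation was at 1.07, hormone-sensing identity at 0.011 in basal cells and 0.043 in fibroblasts, luminal progenitor identity in fibroblasts at 0.024, YAP targets in macrophages at 0.091, and in dendritic cells proliferation at -0.047 and interferon genes at 0.013. With free RNA subtracted, basal chemokines were at 0.055, EMT genes in hormone-sensing cells at 2.97 and hormone-sensing identity in endothelial cells at -0.26. With a pseudocount of 10 CPM, basal cells had basement membrane at -0.15 and proliferation at 0.85. With at least 100 UMIs, EMT genes in macrophages were at 0.00074, and with 1 UMI basal proliferation was at 1.38.

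With mixed barcodes kept, the luminal progenitor share differed by -0.927 points and interferon genes in hormone-sensing cells were at -0.039. With the mixed limit at 5, MHC class II was at 0.070 in luminal progenitors and -0.097 in hormone-sensing cells. Without the proliferating cluster, basal proliferation was at 0.64, and with basal clusters at the control's mix at 0.36. With clusters of the other classes at that mix, MHC class II was at 0.034 in luminal progenitors and -0.11 in hormone-sensing cells, and hormone-sensing identity in macrophages at -0.21. With members under 0.2 of their highest class left out, basal chemokines were at 0.061, contractile genes in endothelial cells at 0.10 and EMT genes in macrophages at 0.066. Luminal progenitors, with 142 and 120 cells, had the fewest UMIs of the 4 main classes (1010304 and 981293).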

Other observations

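The values in this part carry no test, and the lists were chosen for mention after their values were seen. Macrophages and dendritic cells had lower cholesterol synthesis, interferon and chemokine genes in the knockout library. In macrophages all 16 cholesterol synthesis genes lay below the class median (-0.35, -0.47 to -0.23), interferon genes were at -0.30 (15 of 18 below), with Irf7 at -0.73 and Oasl2 at -0.61, and chemokines at -0.31, with Ccl2 at -0.64 (478 and 352 CPM) and Ccl7 at -0.58, but Il1b at 0.48. In dendritic cells cholesterol synthesis was at -0.55 (14 of 15 below), chemokines at -0.78, with Ccl7 at -1.25, and interferon genes at -0.22, with Irf7 at -0.90 and Isg15 at -0.71, while MHC class I genes were at 0.25, with Tap1 at 0.45. The dendritic interferon list ranged from -0.34 with the strict filter to 0.013 after thinning, the macrophage chemokine list was at -0.20 with equal weight per cell, and with a pseudocount of 10 CPM the macrophage lists were at -0.17 (cholesterol synthesis) and -0.19 (interferon). Macrophages had MHC class II genes at 0.20, with H2-DMa at 0.31, and at 0.13 with the strict filter.

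Endothelial cells had lower chemokine genes in the knockout library, at -0.71 (11 of 14 below), with Csf3 at -1.80 (77.5 and 26.4 CPM) and Cxcl10 at 179 and 108 CPM, although Cxcl1 was at 0.41. The finer clusters of the class had unequal mixes, as of 147 control and 289 knockout, 145 and 44, and 56 and 30 cells, and at the control's mix the chemokine list was at -0.92. Their hypoxia genes were at -0.20 (11 of 16 below), with Ddit4 at -0.42, and their dissociation stress genes at 0.19 (18 of 20 above), with Hspa1a at 0.61. Over the other settings the chemokine list ranged from -1.08 to -0.38 and the hypoxia list from -0.25 to -0.089. Their MHC class II list was at -1.62, with Cd74 at 0.02 times the level of the highest class, and was at -0.28 with free RNA subtracted. Dissociation stress genes were above the class median in basal (0.26), luminal progenitor (0.30), hormone-sensing (0.18) and fibroblast (0.19) cells as well.

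A cluster of 87 control and 102 knockout cells had as many luminal progenitor as hormone-sensing genes among its top genes, Wfdc18 and Prlr, and was left without a class. Mixed hormone-sensing barcodes had 32.7 macrophage marker UMIs per 10000 in the control and 41.8 in the knockout, against 1.90 and 0.785 in the other hormone-sensing cells and 92.4 and 110 in macrophages.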
